A study of Rattus norvegicus and Mus musculus with 18 samples.

How the data were processed

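RNA from the 2 tissues of the embryonic kidney was measured on Affymetrix oligonucleotide arrays, 6 with mouse targets and 12 with rat targets. Per the labels' descriptions, kidneys were dissected at embryonic day 12.5 in mouse and 13.5 in rat and treated for 10 min with DNase and trypsin, and the mesenchyme was freed with fine pins. The same descriptions state that mouse bud tips were separated from stalks by dissection, and that inspection and staining with a plant lectin that binds the ureteric bud were used to exclude mixing of bud and mesenchyme. Total RNA was column-purified with DNase digestion and 1 ug of it was labelled by the manufacturer's standard procedure, per the labels, with 2 labelings for each RNA. The 4 deposited tables, 1 for mouse and 1 for each of the 3 rat array designs, hold 1 intensity per probe set and array on a linear scale. The scaling and the summary method behind these values are not given in the sources used here. Every deposited value was above 0. The 2% trimmed means of the arrays in a table differed by 10.4% in mouse and by 2.43%, 4.29% and 4.06% in the rat tables, which is more than the 1% set as the limit for arrays already on a common scale.

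Samples were grouped by their source labels into mouse tip, mouse stalk, mouse mesenchyme, rat bud and rat mesenchyme, with 2 arrays for each tissue and array design. The groupings, tests, thresholds, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Intensities were quantile normalised within each table and transformed to log2(intensity + 16), a scale that understates the change of weakly expressed genes. Control probe sets were then left out, 64 in mouse and 59 in each rat table. A probe set was tested if the mean of at least 1 tissue reached the median of all values in its table, an intensity of 49.3 in mouse and 111, 118 and 115 in the rat tables. This left 23919 of 45037 mouse probe sets and 4616 of 8740, 4657 of 8732 and 4648 of 8730 rat probe sets.

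Differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend. All 6 mouse arrays entered 1 fit, and each rat table was fitted on its own. The 7 comparisons were tip with stalk, tip with mesenchyme, stalk with mesenchyme, the equally weighted mean of tip and stalk with mesenchyme, and bud with mesenchyme on each rat design. A probe set was called when its Benjamini-Hochberg adjusted p was under 0.05 and its difference at least 2-fold, and every adjusted p given for a gene is from these limma fits. In every mouse comparison each tested probe set that differed by 2-fold also had an adjusted p under 0.05, so the fold set the mouse counts, while 56, 22 and 30 rat probe sets differed by 2-fold without passing. A probe set was called restricted to 1 mouse tissue when it was called higher there than in each of the other two. Because such classes share arrays between their comparisons, each count is given with the overlap of independent lists and with the count from 100 simulations of unchanged tissues.

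Probe sets were named from the platform annotation. In mouse 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none. In the first rat design the numbers were 7006, 308 and 1426, in design B 5351, 38 and 3343, and in design C 5821, 45 and 2864. Entrez identifiers of the single-symbol rat probe sets matched the reference table for 6994, 5342 and 5813 of them, and 0 symbols needed an update. Each gene was represented by the probe set with 1 symbol and the highest mean log2 intensity, and probe sets with several symbols were not named.

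Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, over lists with at least 4 tested members, with Benjamini-Hochberg adjustment within each comparison. The same tests were run with a correlation estimated from the data, and with fry, whose p tests whether the genes of a list move, on balance, in 1 direction. The 23 lists covered ureteric bud tip markers, ureteric bud stalk and urothelial markers, ureteric bud and nephric duct genes, epithelial junction and polarity genes, nephron progenitor genes, stromal and interstitial genes, early nephron genes, endothelial markers, erythroid genes, macrophage and leukocyte markers, neuronal and neural crest markers, smooth muscle and ureteric mesenchyme genes, adrenal and gonadal markers, immediate-early and stress genes, cell cycle genes, Wnt/beta-catenin target genes, receptor tyrosine kinase feedback genes, gp130 cytokines and receptors, trunk Hox genes, basement membrane genes, retinoid genes, axon guidance genes, and glycolysis and hypoxia genes. They were written from general knowledge of kidney development, which includes earlier work on this tissue, so the direction of the marker lists is not independent evidence. Imprinted genes, Wnt ligands and modulators, and growth factors were added as lists after the data had been seen.

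Named genes were the 8 called representatives with the largest differences each way and arrays that did not overlap between tissues, for tip with stalk, mouse bud with mesenchyme and the first rat design. The rule added the 5 largest each way for rat designs B and C, up to 4 genes of each list by size of difference, 8 genes for each restricted class, and a fixed set of 14 kidney genes with the controls Actb and Gapdh. Pax2 and Gapdh had no representative probe set and were not analysed here, and 1 other gene of the set is not reported here. Levels are means ± SD of the deposited intensity over the 2 arrays of a tissue.

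Mouse and rat were compared by the direction and size of the bud to mesenchyme difference of genes with the same symbol. Each gene was counted once, on the first of the rat designs that measured it. The mouse and rat tables were normalised separately, so no level was compared between them and no test was made across them.

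The fits were tested on simulated data with 100 probe sets changed at each of 2 sizes. All 100 were recovered at a log2 difference of 2 and of 1.5 in each of the 4 mouse comparisons and on rat designs B and C, while on the first rat design 98 of 100 were recovered at 1.5 and all 100 at 2. False calls numbered 0 of 23919 probe sets in each mouse comparison and 2 of 4616, 2 of 4657 and 1 of 4648 in the rat tables. In the simulations of tip with stalk and of the 3 rat tables, camera called 0 of 100 unshifted lists and 20 of 20 shifted ones. The simulated noise was independent between probe sets, so these runs cannot show how camera performs when the genes of a list are correlated.

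The alternatives were pseudocounts of 1 and 64, median scaling, no filter and a filter at the 75th percentile, eBayes without a trend and robust eBayes, no fold threshold, a treat test against 1.5-fold, probe sets without suffixes for shared targets, the mean of all probe sets of a gene, fits of only the tissues compared, the replicate number as a block, and leaving out each array in turn. Values without between-array normalisation, rat lists without the second bud array and mouse bud without the stalk arrays were added after the data had been seen. No sample was left out of the main comparisons, and 0 columns of values were unused. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.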

Results

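Transcripts of the embryonic kidney were measured on 18 arrays, 6 of mouse and 12 of rat tissue. The metanephric kidney forms from the ureteric bud, an epithelial tube that branches into the collecting ducts, and the metanephric mesenchyme, which gives rise to nephrons and stroma. Mouse tissue at embryonic stage E12.5 was divided into bud tips, bud stalks and mesenchyme, with 2 arrays for each. Rat tissue at stage E13.5 was divided into whole buds and mesenchyme, and each was hybridised to 3 array designs, with 2 arrays per tissue and design. The pools held about 1000 tips, 350 stalks and 300 mesenchymes in mouse and about 1200 buds and 240 mesenchymes in rat. Both arrays of a tissue were labelings of 1 pooled RNA, so the p-values measure only the labelling and hybridisation spread of that RNA, not the spread between animals. The number of arrays limits the precision of all values.

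Over all mouse probe sets, the log2 intensities of the stalk arrays correlated with those of the mesenchyme arrays at r = 0.984 to 0.987 and with those of the tip arrays at r = 0.974 to 0.982. These are correlations across genes, which are not independent replicates. Repeat arrays correlated at r = 0.993 for tips, 0.998 for stalks and 0.996 for mesenchyme. The first of the rat bud labelings correlated with the second at r = 0.981, 0.985 and 0.982 on the first design, design B and design C, and the rat mesenchyme labelings at 0.996, 0.994 and 0.993. The second rat bud labeling had a ratio of 3' to 5' signal for the Gapdh control of 4.43, 5.28 and 4.26 on the 3 designs, while the other rat arrays lay between 1.25 and 1.47. Its 3' signal for the Actb control was 2892 on the first design, against 8761 for the first bud labeling.

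The comparison of tips with stalks asked which transcripts mark the branching ends of the ureteric bud. Ret, the receptor through which the bud responds to GDNF, had an intensity of 1536 ± 155 (SD, n = 2) in tips and 314 ± 1.27 in stalks, a log2 difference of 2.28 (SE 0.10, adjusted p = 1.06e-06). Wnt11, a secreted ligand of branching tips, was at 1362 ± 221 in tips and 306 ± 9.83 in stalks (log2 2.14, adjusted p = 3.85e-07). Slco4c1, an organic anion transporter, had the largest difference among the named tip genes, 2.50, with 331 ± 5.23 in tips and 45.7 ± 5.09 in stalks (adjusted p = 4.42e-06). Aldh1a1, a retinoic acid synthesis enzyme, was higher in tips by 2.02, the arginase Arg2 by 1.96 and the keratin Krt23 by 1.95. In these genes both tip arrays lay above both stalk arrays. In total 1099 of 23919 probe sets were called, 230 higher in tips and 869 higher in stalks, and 145 and 515 genes were represented among them.

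Among the 16 tested ureteric bud tip markers, 11 were higher in tips, with a list median of 1.69 (camera adjusted p = 5.55e-11, adjusted p = 0.0764 with an estimated correlation). For each of the 23 lists in each of the 7 comparisons, the count adjusted over the list alone equalled the count over all tested genes. Both counts need a 2-fold difference, which set the mouse counts, so in mouse this equality carries little information. Receptor tyrosine kinase feedback genes were higher for 4 of 10, including the transcription factors Etv4 (1.94) and Etv5 (1.94) and the pathway inhibitor Spry1 (1.46), with a median of 0.84 (adjusted p = 1.2e-05, adjusted p = 0.0776 with an estimated correlation). Epithelial junction and polarity genes were higher for 7 of 25, among them the splicing regulator Esrp1 (1.44), the trafficking protein Rab25 (1.25) and the tight junction protein Cldn3 (1.14), and the list was shifted by 0.84 (adjusted p = 8.72e-11, adjusted p = 0.0764 with an estimated correlation). The adhesion molecule Cdh1 itself differed by 0.54 and did not pass. The stalk pool also held stromal transcripts, so such differences do not separate expression per epithelial cell from the share of epithelium in each pool. Of 13 ureteric bud and nephric duct genes, 6 were higher in tips, including the calcium-binding protein Calb1 (9574 ± 79.4 in tips, 4310 ± 11.1 in stalks, log2 1.14), and the transcription factor Gata2 was lower (-1.71). That list had a median of 0.54 (adjusted p = 0.00772, adjusted p = 0.113 with an estimated correlation). Gata3, a regulator of the nephric duct, stood at the fold threshold with 1.00, and without the second tip array its difference was 0.97 and no longer called. Of 14 stalk and urothelial markers, Krt23 was called, and it was higher in tips. Krt8 differed by 0.38, Wnt9b by 0.53, Elf3 by 0.44 and Wnt7b by 0.02 (adjusted p = 0.92). This list's median of 0.22 did not pass (adjusted p = 0.0549), although the p was 0.0257 without the second stalk array, 0.0275 without either mesenchyme array, 0.0193 with values as deposited and 0.03 with all representatives.

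The 8 largest differences on the stalk side were in Tbx18, Actc1, Sulf1, Plcxd3, Postn, Pcdh8, Bmper and Matn2, from -4.55 to -3.77. Tbx18, a transcription factor of the mesenchyme around the ureter, was at 54.6 ± 23.3 in tips and 1563 ± 104 in stalks (log2 -4.55, SE 0.20, adjusted p = 8.28e-07). Postn, a matrix protein of connective tissue, was at 72.4 ± 12.8 and 1689 ± 84.3 (log2 -4.29, adjusted p = 2.23e-08), and the cardiac-type actin Actc1 at 55.4 ± 12.4 and 1616 ± 72.4 (log2 -4.51, adjusted p = 2.36e-08). Stromal and interstitial genes were lower in tips for 16 of 21, with a median of -2.37, among them the collagen Col1a1 (-3.50), the growth factor receptor Pdgfra (-3.22) and the stromal regulator Foxd1 (-3.20). The stromal shift had an adjusted p of 2.98e-21, and an adjusted p = 0.0776 with an estimated correlation. Nephron progenitor genes were lower for 8 of 16, including the integrin Itga8 (-2.64) and Hoxa11 (-2.35), the median being lower by 1.00 (adjusted p = 3.51e-07, adjusted p = 0.13 with an estimated correlation). The progenitor regulator Six2 differed by -0.49 and was not called. Of 7 smooth muscle and ureteric mesenchyme genes, 4 were lower in tips, including the myosin light chain Myl9 (-2.47) and the signalling protein Bmp4 (-2.42), with a list median of -1.46 (adjusted p = 2.16e-05, adjusted p = 0.0776 with an estimated correlation). Trunk Hox genes, which pattern the body axis, were lower for 9 of 17 and higher for 1, with Hoxa10 at -2.47, Hoxd10 at -2.25 and Hoxa9 at -2.06, and their median was -1.50 (adjusted p = 0.00778, adjusted p = 0.154 with an estimated correlation).

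**Figure D1:**
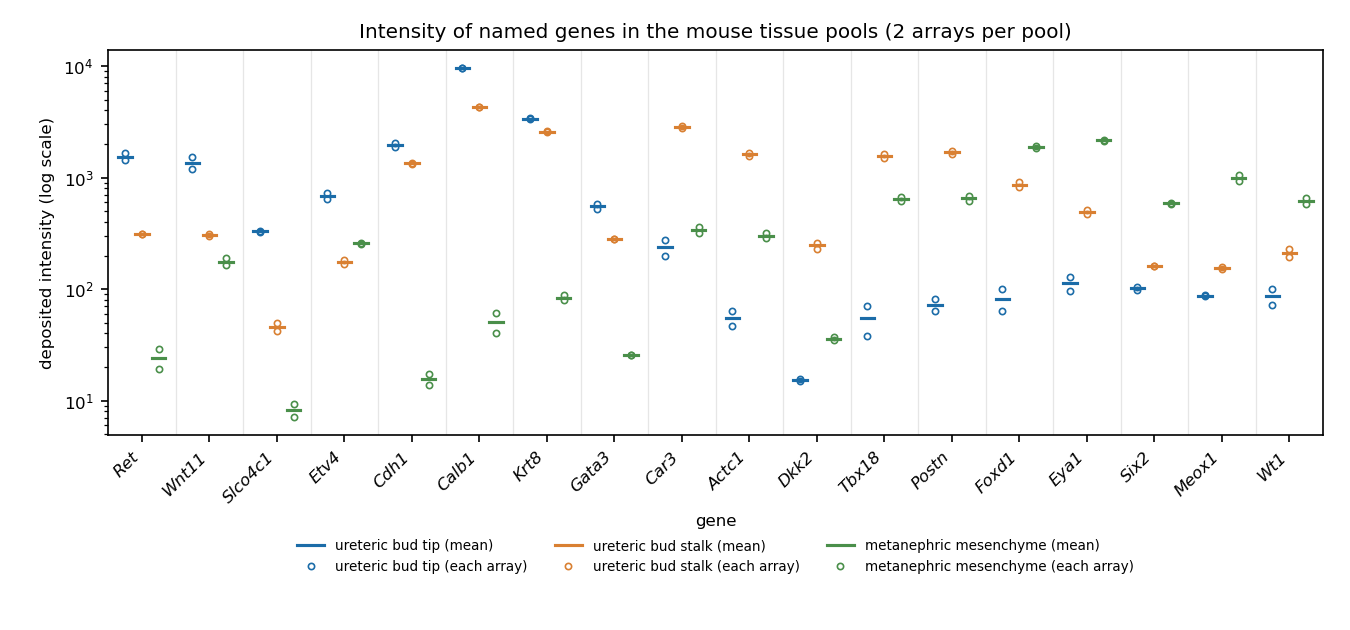
Deposited intensity, on a log axis, of 18 named genes in mouse ureteric bud tip, ureteric bud stalk and metanephric mesenchyme; open circles are the 2 arrays of each tissue and bars their means. Ret is at 1536 in tips and 314 in stalks, while Tbx18 is at 54.6 in tips, 1563 in stalks and 644 in mesenchyme.

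Some markers of cell types other than bud epithelium were lower in tips than in stalks. Endothelial markers were lower for 5 of 12, including the vesicle protein Plvap (-1.58) and the surface glycoprotein Emcn (-1.36), with a median of -0.88 (adjusted p = 2e-05, adjusted p = 0.0776 with an estimated correlation). Erythroid genes were lower for 2 of 7, the embryonic globins Hbb-bh1 (-1.51) and Hba-x (-1.50), with a median of -0.48 (adjusted p = 0.00136, adjusted p = 0.087 with an estimated correlation). Of 13 macrophage and leukocyte markers, the protease gene Ctss was lower (-1.30), and the list median was -0.39 (adjusted p = 0.0125, adjusted p = 0.154 with an estimated correlation). Neuronal and neural crest markers were lower for 2 of 9, the neurofilaments Nefm (-1.51) and Nefl (-1.09), with a median of -0.18 (adjusted p = 0.0275, adjusted p = 0.208 with an estimated correlation). Without the first tip array the neuronal p was 0.0503. With a pseudocount of 64 the differences of Ctss (-0.81), Nefm (-0.84) and Nefl (-0.59) were no longer called. Of 4 gp130 cytokines and receptors, 2 were lower in tips, among them the receptor Lifr (-1.84), which did not pass when all its probe sets were averaged, and the list median was -0.96 (adjusted p = 0.0199, adjusted p = 0.148 with an estimated correlation, 0.11 with all representatives, tested or not). None of the 3 tested adrenal and gonadal markers was called by limma, with 0 at an unadjusted p under 0.05, and Amh, Inha and Star differed by 0.16, 0.13 and 0.13.

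Immediate-early and stress genes were lower in tips for 2 of 17, with a median of -0.40 (adjusted p = 1.84e-05, adjusted p = 0.0776 with an estimated correlation). Fos, an early response transcription factor, was at 2263 ± 198 in tips and 6572 ± 75.7 in stalks (log2 -1.57). None of 22 cell cycle genes reached a 2-fold difference by limma. Of them 14 had an unadjusted limma p under 0.05 and 11 an adjusted one, all 11 higher in tips, so the fold threshold kept these from being called. The list was shifted upwards in tips by a median of 0.17 (camera adjusted p = 0.000489, adjusted p = 0.0776 with an estimated correlation). Glycolysis and hypoxia genes gave a similar picture, with no call among 13. Of these 9 had an unadjusted limma p under 0.05 and 8 an adjusted one, all 8 higher in tips. The list median was 0.43 (camera adjusted p = 0.00117, adjusted p = 0.0858 with an estimated correlation). The glucose transporter Slc2a1 differed by 0.77 and the enzyme Ldha by 0.62. Wnt/beta-catenin target genes were higher in tips for 3 of 11, the receptor Tnfrsf19 (1.15), the stem cell receptor Lgr5 (1.11) and the ubiquitin ligase Rnf43 (1.06). With the mean of all probe sets Tnfrsf19 (0.80), and with a pseudocount of 64 Lgr5 (0.75) and Rnf43 (0.73), were no longer called. The Wnt list did not pass (median 0.23, adjusted p = 0.0541), and its p was 0.0354 without the second tip array, 0.0361 with values as deposited, 0.0461 without the second stalk array and 0.0481 without the first stalk or the second mesenchyme array. Basement membrane genes went both ways, 3 of 19 higher, led by Frem2 (1.61), and 3 lower, with Frem1 (-2.41), Nid2 (-2.17) and Nid1 (-2.04), and their median was 0.30 and their mean 0 (adjusted p = 0.137). Retinoid genes were split as well, with the synthesis enzymes Aldh1a1 (2.02) and Aldh1a3 (1.32) higher and Aldh1a2 (-1.95) and the binding protein Crabp1 (-2.54) lower among 11 tested (median -0.22, adjusted p = 0.127). Axon guidance genes were lower for 4 of 18, including the receptor Unc5c (-1.57) and the Eph receptors Epha3 (-1.95) and Epha7 (-1.70), and higher for 1 (median -0.11, adjusted p = 0.0583), and the p was 0.0485 without the second tip array, 0.0361 with values as deposited and 0.021 with all representatives. Early nephron genes were higher for 2 of 15, Pou3f3 (1.31) and Lhx1 (1.27), and lower for 1 (median 0.18, adjusted p = 0.34).

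**Figure D2:**
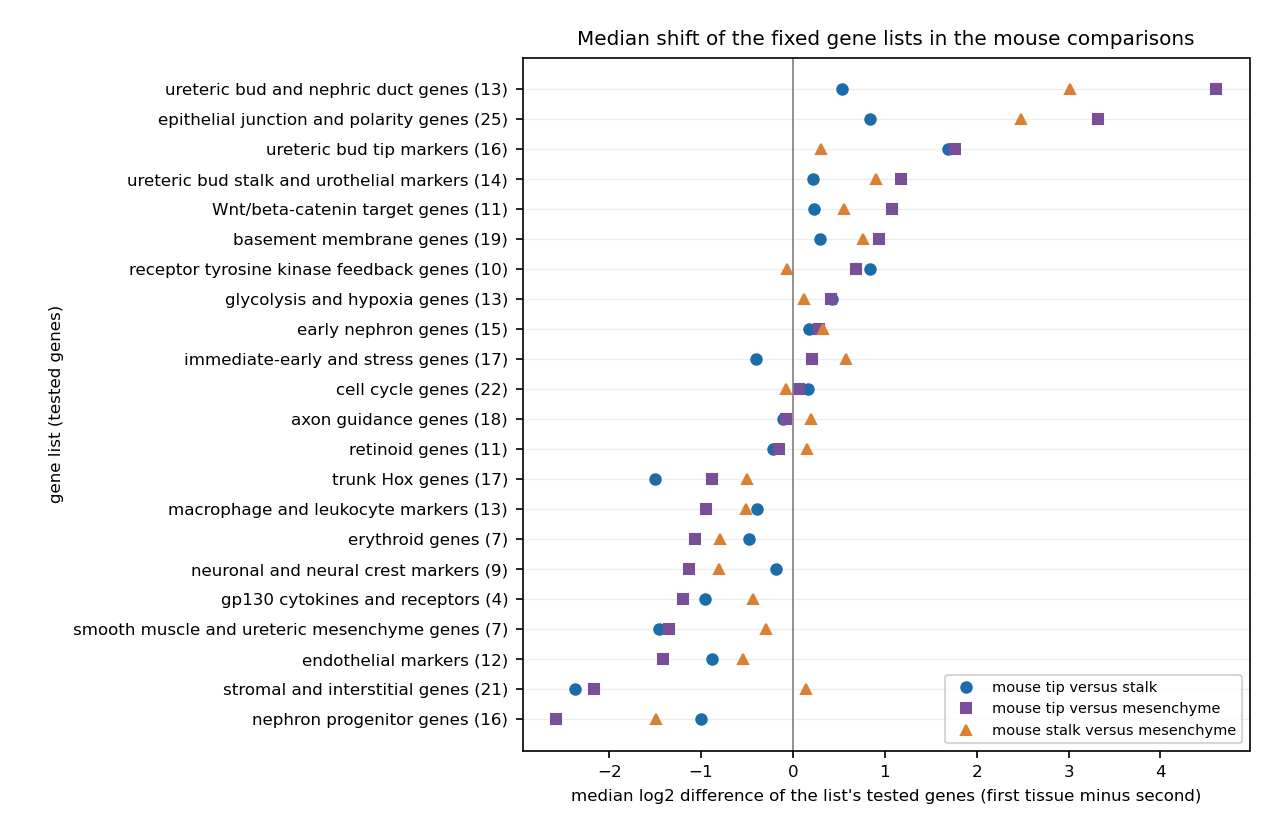
Median log2 difference of the tested genes of each fixed list in the comparisons of mouse tip with stalk (circles), tip with mesenchyme (squares) and stalk with mesenchyme (triangles), with the number of tested genes in brackets. Stromal and interstitial genes lie at -2.37 and -2.16 in the tip comparisons and at 0.14 in stalk with mesenchyme.

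Stalks were next compared with mesenchyme, which asked what the bud trunk expresses that the surrounding tissue does not. Calb1 had the largest difference among the named genes, 6.06, with 4310 ± 11.1 in stalks and 50.6 ± 14.5 in mesenchyme. Cdh1 was at 1339 ± 8.56 in stalks and 15.7 ± 2.55 in mesenchyme (log2 5.42, SE 0.08, adjusted p = 2.31e-09), the tight junction protein Cldn8 at 2405 ± 87.8 and 34.5 ± 3.39 (log2 5.60), and the keratin Krt8 at 2569 ± 35.1 and 83.8 ± 5.52 (log2 4.70). Epithelial junction and polarity genes were higher in stalks for 21 of 25, with a median of 2.48 (adjusted p = 6.91e-35, adjusted p = 0.0172 with an estimated correlation). Nephric duct genes were higher for 11 of 13, with a median of 3.02 (adjusted p = 4.41e-21, adjusted p = 0.0218 with an estimated correlation), and basement membrane genes for 6 of 19, including Npnt (3.06) and Frem2 (2.54), with a median of 0.76 (adjusted p = 1.34e-12, adjusted p = 0.0303 with an estimated correlation). In total 663 probe sets were called, 561 higher in stalks and 102 higher in mesenchyme.

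Nephron progenitor genes were lower in stalks than in mesenchyme for 10 of 16, with Meox1 at -2.64, Eya1 at -2.14 and Six2 at -1.85, and the list median was -1.49 (adjusted p = 1.24e-13, adjusted p = 0.066 with an estimated correlation). Gdnf, the ligand of Ret, was at 151 ± 0.636 in stalks and 404 ± 22 in mesenchyme (log2 -1.40). Stromal and interstitial genes did not move together, with 2 of 21 higher in stalks, Postn (1.34) and Lum (1.29), and 2 lower, Foxd1 (-1.13) and Ntn1, which fell by 2.00. Their median was 0.14 and their mean -0.01 (adjusted p = 0.351). Foxd1 did not pass a test against a 1.5-fold difference (adjusted p = 0.101). Vim, an intermediate filament of mesenchymal cells, was at 4649 ± 158 in stalks and 4841 ± 414 in mesenchyme, a difference of -0.02 (adjusted p = 0.887), and at 1197 ± 1.7 in tips. Among 7 smooth muscle and ureteric mesenchyme genes, Tbx18 (1.23) and the Hedgehog receptor Ptch1 (1.21) were higher in stalks and Des (-1.08) was lower, and the median of -0.29 and the mean of 0.08 differed in sign (adjusted p = 0.679). Tbx18 did not pass a test against a 1.5-fold difference (adjusted p = 0.181), and neither Ptch1 nor Des passed when all probe sets of the gene were averaged. Endothelial markers had a median of -0.54 (camera adjusted p = 1.32e-05, adjusted p = 0.066 with an estimated correlation). No gene of that list was called by limma, while 11 of 12 had an unadjusted p under 0.05 and 7 an adjusted one, all 7 lower in stalks. The globin Hbb-bh1 was lower (-1.17), as was the neuronal gene Stmn2 (-1.57). Immediate-early and stress genes were higher in stalks for 2 of 17, the chaperone Hspa1b (1.48) and the transcription factor Klf6 (1.27), with a median of 0.58 (adjusted p = 4.06e-10, adjusted p = 0.0575 with an estimated correlation).

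Tips compared with mesenchyme gave the most calls, 1952 probe sets, 932 higher in tips and 1020 higher in mesenchyme. Calb1 was at 9574 ± 79.4 in tips and 50.6 ± 14.5 in mesenchyme, a log2 difference of 7.20 (SE 0.13, adjusted p = 2.28e-09), Cdh1 differed by 5.96 and Ret by 5.29. Epithelial junction and polarity genes were higher in tips for 24 of 25, with a median of 3.32 (adjusted p = 7.05e-23, adjusted p = 0.0325 with an estimated correlation). Tip markers were higher for 11 of 16 (median 1.76, adjusted p = 1.62e-11, adjusted p = 0.0494 with an estimated correlation), and nephric duct genes for 10 of 13 (median 4.61, adjusted p = 1.62e-11, adjusted p = 0.0494 with an estimated correlation). Nephron progenitor genes were lower in tips for 13 of 16 (median -2.58, adjusted p = 7.03e-11, adjusted p = 0.0767 with an estimated correlation). Stromal genes were lower for 17 of 21 (median -2.16, adjusted p = 1.77e-16, adjusted p = 0.0767 with an estimated correlation), with Foxd1 at 81.4 ± 25.9 in tips and 1890 ± 61.3 in mesenchyme (log2 -4.34). Endothelial markers were lower for 9 of 12 (median -1.41, adjusted p = 6.85e-07, adjusted p = 0.0682 with an estimated correlation) and erythroid genes for 4 of 7 (median -1.06, adjusted p = 6.1e-05, adjusted p = 0.0682 with an estimated correlation). Retinoid genes had a median of -0.15 and a mean of 0.14, and their test did not pass (adjusted p = 0.575).

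Transcripts restricted to 1 mouse tissue were sought next, since the labels name a screen for spatially restricted transcripts. Tip-restricted probe sets, higher in tips than in both other tissues, numbered 212 and represented 138 genes. They were led by Slco4c1, Hs3st3b1, Ret, Wnt11, Ctnnd2, Aldh1a1, Arg2 and Krt23, of which the sulfotransferase gene Hs3st3b1 did not pass against stalk when all its probe sets were averaged (0.86). The class does not require absence from stalks, since Esrp1, a member, was at 1770 in tips, 653 in stalks and 24 in mesenchyme. In the stalk pool, which also held stromal transcripts, epithelial genes covered a median of 0.501 of the difference from mesenchyme to tip. Genes of the whole bud epithelium can therefore fall in this class. Stalk-restricted probe sets numbered 71, for 40 genes. Car3, a carbonic anhydrase of muscle and fat, was at 2825 ± 66.3 in stalks, 236 ± 52.6 in tips and 340.0 ± 31.6 in mesenchyme, which gave log2 differences of -3.49 for tip with stalk and 2.99 for stalk with mesenchyme. Actc1 was higher in stalks than in mesenchyme by 2.32, Plcxd3 by 2.51, the secreted Wnt modulator Dkk2 by 2.29, Gata2 by 1.73 and the peptidase Enpep by 2.08. Mesenchyme-restricted probe sets numbered 91, for 66 genes, and were led by the homeobox genes Meox1 and Meox2, the arginase Arg1, the muscle-type actinin Actn3, the transcriptional regulator Eya1, the Wnt agonist Rspo1 and the thyroid hormone-binding protein Crym. Meox1 was at 995 ± 78.6 in mesenchyme, 154 ± 3.75 in stalks and 87.5 ± 1.41 in tips. Independent lists of the same sizes would share 8.96, 20.4 and 4.35 probe sets, and 100 simulations of unchanged tissues on shared arrays gave at most 1, 0 and 0. The shared arrays, 2 per tissue, were not split between the comparisons, so part of each excess may come from them.

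The mean of tips and stalks was compared with mesenchyme to give a whole-bud difference for mouse. The 8 largest bud differences were in Calb1 (6.63), Cdh1 (5.69), Cldn8 (5.65), Cldn4 (5.07), Krt8 (4.89), Cldn6 (4.79), Krt18 (4.79) and Esrp1 (4.77). On the mesenchyme side the 8 largest were Arg1 (-3.24), Meox2 (-3.12), Eya1 (-3.11), Crabp1 (-3.02), the Wnt agonist Rspo3 (-2.99), Meox1 (-2.96), the tropomyosin Tpm2 (-2.86) and Crym (-2.85). Of 23919 probe sets 1110 were called, 688 higher in bud and 422 higher in mesenchyme. Ret was higher in bud by 4.16, with 1536 in tips, 314 in stalks and 24.1 ± 6.93 in mesenchyme, and Gdnf was lower (-1.85). Wnt7b differed by 0.87 and was not called. Vim stood at the threshold, lower in bud by 1.00, and was not called without the first mesenchyme array (-0.90). Epithelial genes were higher for 23 of 25 (median 2.98, adjusted p = 2.91e-29, adjusted p = 0.0224 with an estimated correlation), nephron progenitor genes lower for 13 of 16 (median -1.98, adjusted p = 1.15e-12, adjusted p = 0.071 with an estimated correlation) and stromal genes lower for 10 of 21 (median -0.98, adjusted p = 9.52e-14, adjusted p = 0.0809 with an estimated correlation). Over the 120 list tests of all comparisons, 86 passed with the preset correlation and 8 with an estimated one. Those 8 were the epithelial and nephric duct lists of all 3 mouse comparisons with mesenchyme, the tip markers of tip with mesenchyme and the basement membrane genes of stalk with mesenchyme.

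Rat buds were compared with rat mesenchyme on the first design. Aldh1a1 was at 5174 ± 800 in buds and 139 ± 9.55 in mesenchyme (log2 5.03, adjusted p = 2.6e-05), the epithelial adhesion molecule Epcam differed by 4.32, Krt18 by 4.59 and Arg2 by 3.80. Ret was at 1601 ± 425 in buds and 124 ± 0.849 in mesenchyme (log2 3.52, adjusted p = 0.000128). On the mesenchyme side the imprinted transcript H19 differed by -3.26, the retinoid-binding protein Crabp1 by -3.68, the nuclear receptor Nr2f1 by -3.18 and Foxd1 by -2.92. Of 4616 probe sets 267 were called, 127 higher in buds and 140 higher in mesenchyme, and 477 were called without the first bud labeling, when the bud was represented by the labeling with the high Gapdh ratio. Nephric duct genes were higher for 5 of 9 (median 1.73, adjusted p = 4.7e-05) and tip markers for 4 of 7 (median 1.44, adjusted p = 6.97e-05), each with an adjusted p = 0.158 with an estimated correlation. Epithelial genes were higher for 4 of 8 (median 1.01, adjusted p = 5.02e-06), nephron progenitor genes lower for 4 of 5 (median -2.16, adjusted p = 9.35e-08) and stromal genes lower for 9 of 14 (median -1.76, adjusted p = 6.51e-13), again each with an adjusted p = 0.158 with an estimated correlation. The progenitor genes that were lower included Wt1 (-2.60), Uncx (-2.16) and Cited1 (-1.64). Erythroid genes had a median of -0.28 (adjusted p = 0.0254, adjusted p = 0.233 with an estimated correlation), but the p was 0.0584 without the second bud labeling, 0.123 without the first and 0.0618 without the first mesenchyme labeling. Other globin genes, outside that list, were among the largest differences, Hbg1 at -3.11 and Hbe1 at -2.94. Gata3 differed by 0.02 on this design, Gdnf by -0.48 (adjusted p = 0.0548) and Actb by -0.71 (adjusted p = 0.122).

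On rat design B the retinoic acid synthesis enzyme Aldh1a3 had the largest difference, 4476 ± 247 in buds against 37.4 ± 1.91 in mesenchyme (log2 6.28, adjusted p = 1.57e-05). Cdh1 (4.09), the duct transcription factor Emx2 (3.76), Esrp1 (3.50) and the tubulin Tubb2b (3.23) followed, and the nuclear receptor Nr2f2 (-4.22), Wt1 (-3.85), the globins Hbz (-3.65) and Hba-a1 (-3.08) and the transcription factor Foxc2 (-3.15) led the mesenchyme side. Epithelial genes were higher for 6 of 8 (median 1.77, adjusted p = 9.89e-09) and nephron progenitor genes lower for 3 of 4 (median -2.23, adjusted p = 1.31e-05), each with an adjusted p = 0.19 with an estimated correlation. Erythroid genes were lower for 2 of 4 (median -1.49, adjusted p = 0.000795, adjusted p = 0.19 with an estimated correlation), and endothelial markers for 1 of 4, Cdh5 (-2.32), with a list median of -0.53 (adjusted p = 0.00328, adjusted p = 0.303 with an estimated correlation). Cell cycle genes had a median of 0.40 (adjusted p = 0.0315, adjusted p = 0.276 with an estimated correlation), and the p was 0.059 without the second bud labeling and 0.0548 without the second mesenchyme labeling, and 0.183 with the mean of all probe sets of a gene. Retinoid genes had a median of -0.12 and a mean of 1.01, and their test did not pass (adjusted p = 0.749). In total 142 probe sets were higher in buds and 127 higher in mesenchyme, of 4657.

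On design C Epcam had the largest difference, with 1678 ± 6.08 in buds and 34.0 ± 0.354 in mesenchyme (log2 5.07, adjusted p = 0.000116), followed by the Kit ligand gene Kitlg (4.06), Gata3 (3.58), the membrane protein Mal2 (3.57) and the protease Prss23 (3.57). The Gata3 probe set of this design thus differed by 3.58, while another probe set, on the first design, differed by 0.02 (203.6 in buds, 203.4 in mesenchyme). The matrix genes Spock2 (-3.87), Tgfbi (-3.25) and Mfap4 (-2.70), the chemokine Cxcl12 (-2.88) and the glutathione transferase Gsta4 (-2.47) were highest on the mesenchyme side. Endothelial markers were lower in buds for 2 of 4 (median -0.94, adjusted p = 0.000514, adjusted p = 0.311 with an estimated correlation). These were Cdh5 and Emcn, and neither was called without the first mesenchyme labeling (adjusted p = 0.0618 and 0.0672). Of 7 stromal genes, each represented by 1 probe set, no representative was called by limma. The list median was -0.48 (adjusted p = 0.00424, adjusted p = 0.311 with an estimated correlation). Other probe sets of these genes were called, since only 1 of 5 tested for Col1a2 and 1 of 2 for Col3a1 were uncalled. The desmosomal gene Dsp differed by -0.03 and was not called, but the mean of all its probe sets differed by 1.64 (adjusted p = 0.00142). Of 4648 probe sets 103 were higher in buds and 112 higher in mesenchyme, and the total of 215 depended on single arrays, with 77 without the first mesenchyme labeling, 82 without the second and 360 without the first bud labeling.

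Mouse and rat were set side by side by direction and size only, since their tables were normalised separately. Over 9829 genes measured in both, 5558 differed in the same direction, 56.5% (95% Wilson interval 55.6 to 57.5), with r = 0.466 and Spearman's rho = 0.28 across genes. These genes include those under the filter level. Of the 6041 tested in both species 3474 went the same way, 57.5%. The interval treats genes as independent, which they are not, and covers no spread between animals. With each gene counted once, on the first rat design that measured it, 135 genes were called in both species. Of these, 132 went the same way, 80 higher in bud and 52 higher in mesenchyme. Genes called alike in mouse and rat included, on the bud side, Aldh1a3 (3.98 in mouse, 6.28 on rat design B), Cdh1 (5.69, and 4.09 on design B) and Ret (4.16, and 3.52 on the first design). On the mesenchyme side they included, with the first rat design, Crabp1 (-3.02 and -3.68), Foxd1 (-2.74 and -2.92) and Wt1 (-2.10 and -2.60, with -3.85 on design B). Taken design by design, 67 of 67 genes called in both went the same way on the first design, 57 of 59 on design B and 45 of 48 on design C. The 5 opposite pairs of gene and design were in Ccn2, Rdh10, Crym and Sat1. Rdh10 is not among the 135 genes, since its probe set on the first design (0.57) was not called. Mouse tissue was taken at E12.5 and rat tissue at E13.5, so species and stage changed together. The bud sample changed with them, being the equally weighted mean of tip and stalk pools in mouse and whole buds in rat.

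**Figure D3:**
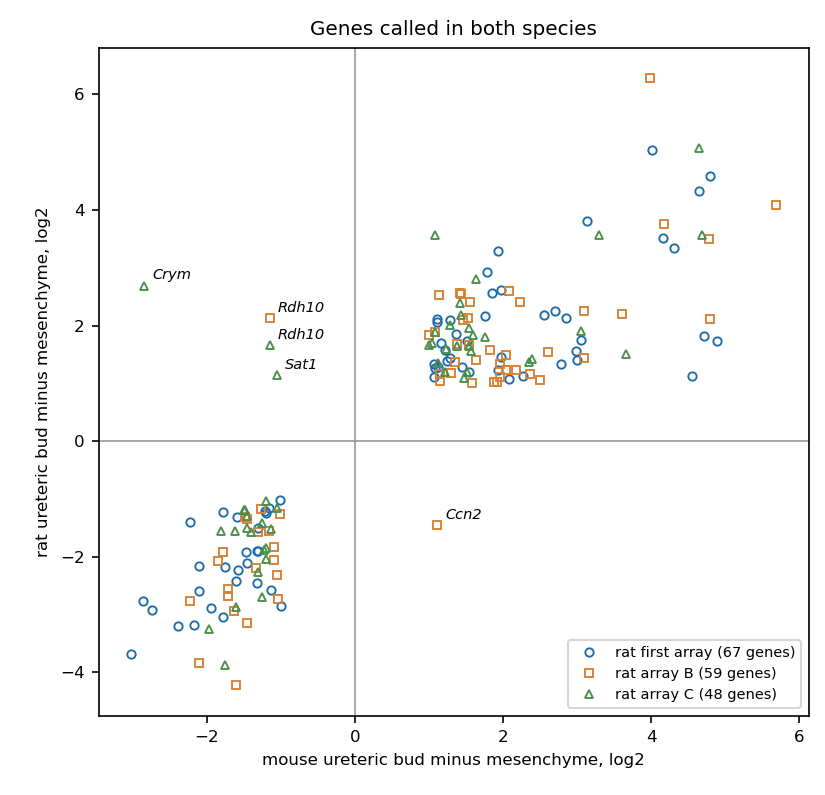
Log2 difference of bud and mesenchyme in rat against that in mouse for genes called in both, with 67 genes on the first rat design (circles), 59 on design B (squares) and 48 on design C (triangles). All 67 genes of the first design share their direction, and the 5 labelled points are the gene and design pairs with opposite calls.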

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

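The checks of the second bud labeling and of other probe sets were set before their results were seen. No test in this part was chosen afterwards.

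In 5 pairs of gene and rat design the call in rat was opposite to that in mouse, with every bud array on the same side of every mesenchyme array in rat. Ccn2 was higher in mouse bud (1.11) and lower in rat bud on design B (-1.46). Rdh10 was lower in mouse bud (-1.15) and higher in rat bud on design B (2.13) and on design C (1.66). Crym was lower in mouse bud (-2.85) and higher in rat bud on design C (2.69), and Sat1 was lower in mouse bud (-1.05) and higher in rat bud on design C (1.14). The difference between the species was not tested, since the tables were normalised separately.

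With the first rat bud labeling alone 5 of the 5 pairs still differed by 2-fold or more in the rat direction (log2 -1.57 for Ccn2 and 1.13 to 2.98 for the others), which argues against the second rat bud labeling, with its high Gapdh 3' to 5' ratio, as the cause. Probe sets that do not measure the named gene could also produce opposite calls, but 0 other called probe sets opposed the pairs, and only Rdh10 had another called probe set, in mouse (-1.14). A second Rdh10 probe set on rat design B (-0.10) and 1 on the first rat design (0.57) were not called, so this explanation cannot be told from a real difference. Of these genes only Crym was refitted with single rat arrays left out, and its call was lost without the second rat mesenchyme labeling (2.54). How far the calls of Ccn2, Rdh10 and Sat1 rest on a single mesenchyme array was not examined. The mesenchyme intensities of Sat1, 89.2 and 64.6, lay below the filter level of 115 on design C. A difference of species or of stage, E12.5 against E13.5, could also produce opposite directions and was not tested. The same holds for the bud sample, a mean of tip and stalk pools in mouse and whole buds in rat. For Crym both mouse pools lay below mesenchyme, at 41 in tips and 141 in stalks against 637.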

How the results depend on the processing

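Values refer to the number of called probe sets unless stated, and the cause of each change was not tested except where the threshold itself sets it. A pseudocount of 64 lowered tip with stalk from 1099 to 671, tip with mesenchyme to 1266, stalk with mesenchyme to 393, mouse bud with mesenchyme to 658, rat design B to 172, and the tip-, stalk- and mesenchyme-restricted sets to 131, 37 and 52. A filter at the 75th percentile gave 1285 for tip with mesenchyme, 46 stalk-restricted probe sets, 176 on rat design B and 57.7% of genes in the same direction in both species. Without a fold threshold, which by construction adds calls, the counts were 6847, 8059, 3128 and 5993 in the mouse comparisons in the same order, 539, 808 and 521 on the rat designs, and 2411, 528 and 821 for the restricted sets. A test against a 1.5-fold change gave 160, 164 and 127 on the rat designs. Agreement of direction among genes called in both species, each counted once, was 97.8%. Tip arrays alone against mesenchyme, an alternative chosen after seeing the data, gave 1931 for mouse bud with mesenchyme. Of 86 list shifts 8 remained with an estimated correlation. The difference of Dsp on rat design C turned from -0.03 to 1.64 with the mean of all its probe sets. Leaving out 1 array at a time gave 243 to 477 on the first rat design, 228 to 370 on design B and 77 to 360 on design C, and the arm with 1 array left is assumed to vary like the others. With the labeling number as a block, the rat counts were 306, 274 and 224. The mouse counts of 1099, 1952, 663 and 1110 are fixed by the fold, which a balanced block leaves as it is, and at an adjusted p under 0.05 alone the block gave 10020, 10345, 5414 and 8235. For the pairing, the labels give the 2 arrays of each tissue only a shared number, and deviations of the first labelings from their tissue means correlated across genes at 0.466, 0.566 and 0.423 in mouse and 0.309, 0.222 and 0.293 in rat. Among values of named genes under the alternatives, 11471 kept their side of the threshold without a reversed call, 61 of them uncalled values whose sign changed, 196 became called and 190 were no longer called.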

Other observations

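The lists of imprinted genes, Wnt ligands and modulators, and growth factor ligands, and the tests of the stalk pool and of the second rat bud labeling, were chosen only after the results they concern had been seen.

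Imprinted genes, which are expressed from 1 parental copy and often regulate growth, were lower in tips than in stalks for 4 of 18 (Meg3 -1.72, Rian -1.64, Dlk1 -1.54 and Cdkn1c -1.34). On the first rat design 4 of 10 were lower in buds than in mesenchyme (H19 -3.26, Igf2 -2.41, Plagl1 -2.06 and Nnat -1.77), and on design B Cdkn1c was lower (-2.57), while on the first design it differed by -0.07 and was not called. In mouse bud against mesenchyme 2 of 18 were lower, Dlk1 (-1.54) and Meg3 (-1.26), and Cdkn1c (-0.92), Nnat (-0.64), Igf2 (-0.43) and Plagl1 (0.05) were not called. Neither Dlk1 nor Meg3 was among the imprinted genes called in rat. Among 19 Wnt ligands and secreted modulators, the ligands Wnt11 (2.14) and Wnt6 (1.25) were higher in tips, and 6 modulators were lower, led by Dkk2 (-3.03), Sfrp2 (-2.43) and Rspo3 (-2.28). In mouse bud against mesenchyme Wnt9b (2.71), Sostdc1 (1.98), Wnt11 (1.75), Wnt6 (1.28) and Dkk3 (1.09) were higher and Rspo3 (-2.99), Rspo1 (-2.72) and Frzb (-1.20) lower. In rat, Sostdc1 (2.62) and Wnt6 (2.02) were also higher in buds and Frzb (-2.04) lower, but Wnt9b (0.85), Dkk3 (0.37) and Rspo3 (-0.40) were not called. Sfrp2 was lower in rat buds (-1.87) and not called in mouse bud (-0.21), a mean over tips and stalks, between which it differed by -2.43. Of 23 growth factor ligands, 5 were lower in tips than in stalks, led by Tgfb2 (-2.77), Cxcl12 (-2.51) and Bmp4 (-2.42), and 2 were higher, Tgfa (1.01) and Bmp7 (1.00). In mouse bud against mesenchyme Kitl (2.10) and Shh (1.97) were higher and Gdnf (-1.85), Tgfb2 (-1.69), Cxcl12 (-1.61), Igf1 (-1.54) and Fgf20 (-1.02) lower. The rat Kit ligand gene Kitlg differed by 4.06 on design C, where the Ret-family ligand Nrtn differed by 2.15, and Cxcl12 (-2.88), Bmp4 (-2.29) and, on the first design, Igf2 (-2.41) were lower in rat buds. Bmp4 was not called without the second mesenchyme labeling (-2.09). Shh in rat (-0.02) and Nrtn in mouse bud against mesenchyme (0.11) were not called. Bmp4 was likewise not called in mouse bud against mesenchyme, and neither Igf1 nor Tgfb2 was called in rat.

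The stalk pool held stromal transcripts beside epithelial ones. For genes lower in tips than in mesenchyme, the stalk level covered a median of 1.12 of the difference from tip to mesenchyme in stromal genes (17 genes, 0.119 to 2.947) and of 0.217 in nephron progenitor genes (13 genes, 0.064 to 0.69), while epithelial genes covered 0.501 of the difference from mesenchyme to tip. For the genes of these lists in this stalk pool, the difference of the medians argues against carry-over of whole metanephric mesenchyme as the whole cause (permutation p = 0.00053). The p permutes genes between the stromal and progenitor lists. Genes are not independent, so the p may be too small, and it covers no spread between pools or dissections. A mixture of only tip-like epithelium and metanephric mesenchyme would lie between the levels of its 2 parts. The 71 stalk-restricted probe sets, of 23919 tested, argue against such a mixture as the whole cause. A mixture with a further source added remains open. The simulated maximum of 0 was for unchanged tissues with labelling noise, and no mixture was simulated. For smooth muscle and ureteric mesenchyme around the stalk, 2 of 7 genes were higher in stalks than in mesenchyme and 1 was lower, too few to tell. Mesenchyme carried with the stalk could account for part of the pattern, as could expression by stalk cells themselves, and a stain for Tbx18 or Postn on sections would separate these.

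The second rat bud labeling lay apart from the first on all 3 designs. Its Gapdh 3' to 5' ratio was at least 4.26, against at most 1.47 on the other rat arrays, as shorter target or degraded RNA would give. Degradation of the shared pool before labelling would have affected both labelings, so it would have to concern the second alone. Mesenchyme RNA in the first labeling alone would go against the design, in which both labelings came from 1 pooled RNA, so a test of it adds little. In that test 125 rat genes called higher in mouse mesenchyme had a median excess of 0 in the first labeling over the second (95% bootstrap interval -0.06 to 0.03, permutation p = 0.972). The interval and the p resample genes, which are not independent. The first labeling did correlate more closely with the mesenchyme arrays than the second, at 0.970 and 0.968 against 0.948 and 0.951 on the first design. The order was the same on designs B and C. No biological explanation was tested, since both labelings came from 1 pool.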
